A study of Homo sapiens with 6 samples.

How the data were processed

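The series holds 6 mRNA-seq libraries of MCF-7 cells, 3 labelled control and 3 labelled as given vitamins A and D together. Per the labels' protocols, cells grew in a minimal essential medium with 10% fetal bovine serum and 1% antibiotic, libraries were made with a poly(A) mRNA kit, and paired reads of 50 nt were sequenced on a NovaSeq 6000. The label text that gives 1.5 mcg/ml and 4 h stands on the control samples too, so the groups were taken from the treatment label and the sample titles. Replicate numbers 1 to 3 follow accession order and pair no samples.

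The deposited file holds raw counts per Ensembl gene, whole numbers with no normalization. Per the labels' protocols, the authors aligned reads to hg38 with STAR and BWA MEM and counted Ensembl genes with featureCounts, and the submitters' processing notes name STAR, featureCounts and edgeR. Versions, the annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. The file lists 43836 genes, of which 43177 matched GENCODE release 44 on hg38 by stable identifier and 32760 took a symbol. The 659 unmatched genes stayed in the counts without a symbol, and 19793 genes had 0 counts in all libraries. Coordinates, transcript GC content and exon overlaps come from that annotation, which can differ from the release the authors used. No row lacked a gene, and no column was left out. Because strand handling is not stated, counts of genes whose exons overlap a gene on the other strand are uncertain: among named genes the overlap was over 10% of exon length for CP, KRT18, BAD, FOXM1, JUNB, CCND1, FBP1 and IRF1. CTSD, MT1X and RPS2 overlap another annotated gene on their own strand. Near-identical paralogs and pseudogenes (HSPA1A, HBA1, metallothioneins, histones, AKR1C genes, ribosomal proteins) are uncertain in the same way.

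The main test was fixed before the data were examined: edgeR 4.0.16 in R 4.3.3, TMM normalization, filterByExpr by group (14708 genes kept), the quasi-likelihood F-test of treated minus control over all 6 libraries with no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors are Wald errors of the log2 fold change from the fitted dispersions. CPM values are TMM-normalized and given as mean ± SD over 3 libraries. Total counts per library were 29307054, 28717019 and 29590800 in control and 34713047, 33247298 and 32205869 in treated cells. The common biological coefficient of variation was 3.79%, low enough that small changes pass the test. Where a group had 0 counts the fold is a bound against 3 counts over the group, and where it had 1 to 3 the ratio has an exact 95% interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

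Gene lists, 36 in all, were fixed before the data were examined, together with the rule for named genes. That rule takes the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM, a symbol and fully separated groups. It adds 16 fixed genes, up to 4 members per list with the smallest adjusted p, and the 6 smallest adjusted p overall. Genes named outside it are said to be chosen after their values were seen. Lists with at least 5 tested members (32) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Some genes belong to several lists.

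Alternatives fixed beforehand were DESeq2 size factors within edgeR, no low-count filter, a filter of 1 CPM in 3 libraries, each library left out in turn, DESeq2 1.42.0, limma-voom, a threshold of 0.01, a test against a log2 fold change of 0.5, protein-coding genes only, camera with estimated correlations (which also tests on the residual degrees of freedom of the 6 libraries, fewer than with a preset correlation), and fry. After seeing the data 2 more were added: a GC correction, in which the lowess trend of each library's log2 counts on transcript GC content (span 0.5) entered edgeR as an offset, and scaling by library totals. On counts simulated from these libraries (14515 genes), edgeR recovered 64% of genes changed 1.25-fold, 74% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 3.53% of its calls were unchanged genes. Only 199 of the simulated genes were changed, so the 3.53% does not carry over to data in which 78.6% of genes were called. With a GC trend added to the simulation (14494 genes before and 14413 after correction) Spearman's rho of fold change with GC went from -0.93 to -0.022 under the correction. In that simulation 98.3% of uncorrected calls were genes changed by nothing but the trend, against 5.33% of corrected calls. Camera, its estimated-correlation form and fry each called a simulated list raised 1.5-fold and 0 of 30 unchanged lists. Genes were simulated independently and without a trend there, so this cannot test the preset correlation or lists of correlated members. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.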

Results

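Polyadenylated RNA was sequenced from MCF-7 cells, an established estrogen receptor-positive line of human breast cancer with luminal features. The 6 libraries fell into 2 groups of 3: control cells, and cells given vitamins A and D together. Vitamin A is the precursor of retinoic acid, which acts through the RAR and RXR nuclear receptors, and the active form of vitamin D acts through the VDR nuclear receptor. The labels give 1.5 mcg/ml and 4 h for the combination, and do not state the chemical form of either vitamin, the vehicle or the share of each in the dose. The comparison of treated with control cells addressed which transcripts differed between the groups. Neither vitamin was given alone, so no value can be assigned to one of them. The labels also do not state whether control cells received vehicle or matched the treated cells in density and passage, so the values are differences between the groups as labelled. The deposited counts summed to between 28717019 and 29590800 per control library and between 32205869 and 34713047 per treated library. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries of a group nonetheless differed by more than counting noise, with a chi-square per degree of freedom of 2.26 to 4.84 against 307.7 to 332.7 between groups.

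Most measured genes differed between the groups. Among gene lists called by camera with a preset correlation, none of which passed with an estimated one, inflammatory, retinoic acid, vitamin D and endoplasmic reticulum stress genes mostly rose and histone, DNA replication, cholesterol synthesis and estrogen receptor target genes mostly fell. Of 14708 genes tested, 11554 (78.6%) changed, with 5970 higher and 5584 lower in treated cells. The changes were mostly modest: the median changed gene rose 1.73-fold or fell 1.70-fold, 4114 genes changed at least 2-fold (2142 higher, 1972 lower) and 870 at least 4-fold (495 higher, 375 lower). In 11742 genes (79.8%) every treated library lay on the same side of every control library, where chance gives 10%. The first principal component held 86.9% of the variance and separated the groups. Control libraries concentrated 9.69% to 9.78% of their counts in their 10 most abundant genes and treated libraries 6.87% to 7.32%. Scaling by library totals in place of the trimmed mean of M-values (TMM) moved the median log2 fold change of all tested genes from 0.04 to 0.36 and the split to 7901 higher and 3788 lower genes, or 67.6% higher against 51.7%. Changes are therefore given relative to the TMM center. The fold changes also ran with base composition: among protein-coding genes the median log2 fold change was 0.77 in the tenth of genes with the lowest transcript GC content (median 36.8%) and -0.83 in the tenth with the highest (median 64.4%). Removing the GC trend of each library, an alternative chosen after seeing the data, left 10645 changed genes. Of these, 9306 were among the 11554, and 8140 of the 9306 kept their direction. Genes changed at least 2-fold numbered 2779 with the GC correction and 4717 with library totals, against 4114 in the main fit.

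**Figure D1:**
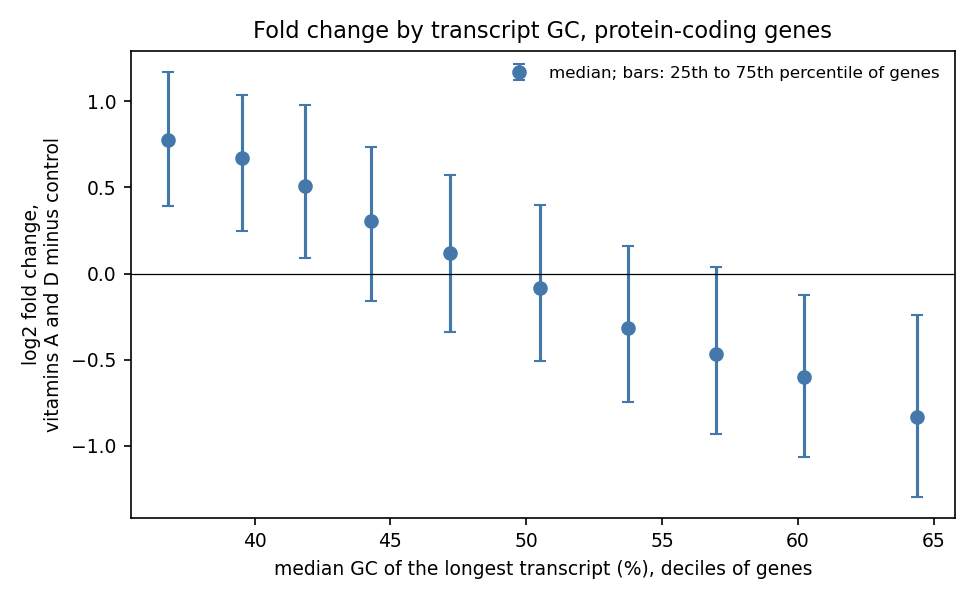
Median log2 fold change (treated minus control, vertical axis) of protein-coding genes in 10 equal groups by GC content of the longest transcript (horizontal axis, percent), with bars from the 25th to the 75th percentile of genes. The median falls from 0.77 at a median GC of 36.8% to -0.83 at 64.4%.

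Gene groups were read from 36 lists fixed before the data were examined, of which 32 had at least 5 tested members. Limma's camera test, which compares the members of a list with all other genes, called 14 lists at an adjusted p under 0.05, with 6 higher and 8 lower. None of the 14 passed when the correlation between members was estimated from these 6 libraries, and the p obtained that way is given beside each. Member counts adjusted over the list alone equaled those over all genes tested, except that luminal identity then had 4 higher members in place of 3. Beside the genes said below to be named after their values were seen, the following were too: RET, NRIP1, GATA3, FOXA1, EPCAM, ATF4, ATF5, PHGDH, SHMT2, G6PD, TKT, TALDO1, MT2A, SC5D, HSD17B7, ABCG1, CDK6, CDC6, TOP2A, MT-ND5 and COL3A1.

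**Figure D2:**
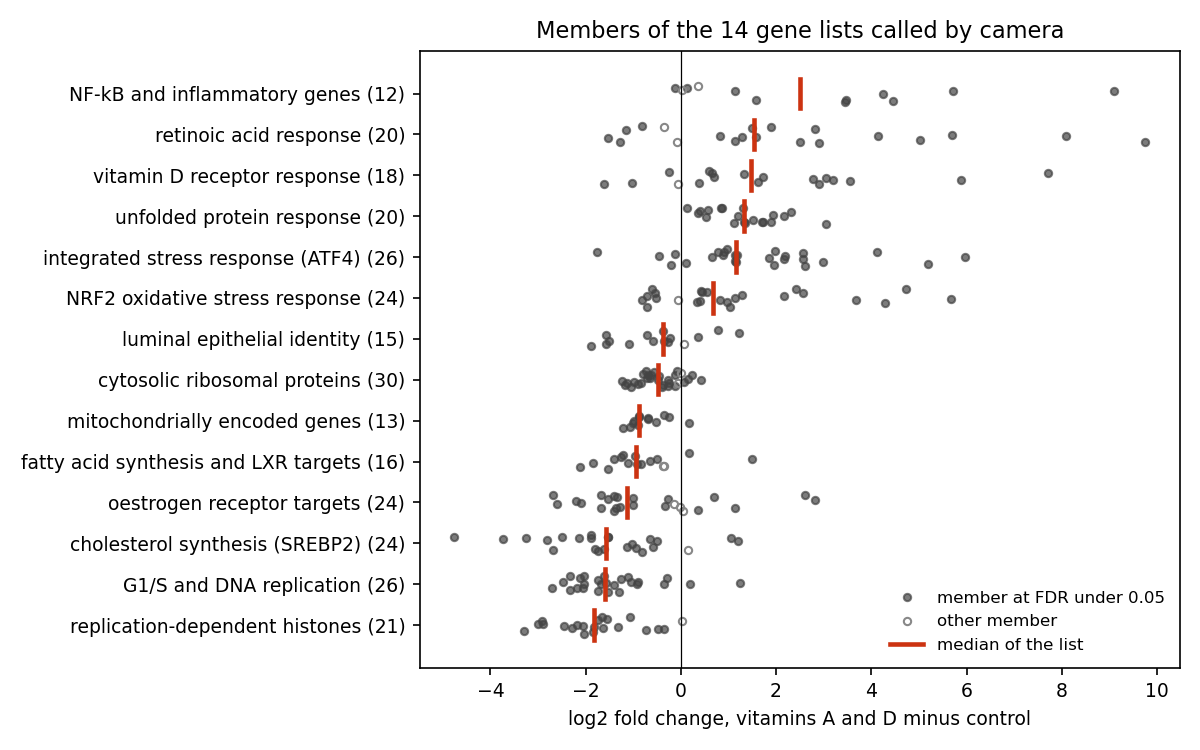
Log2 fold change (treated minus control, horizontal axis) of each tested member of the 14 lists called by camera, with the number of tested members in parentheses. Each point is a gene, filled where its adjusted p was under 0.05, and the red bar is the median of the list. Medians ran from -1.82 for replication-dependent histones to 2.51 for NF-kB and inflammatory genes, and each list except the unfolded protein response and the histones held members that changed in both directions.

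Genes of the retinoic acid response mostly rose. CYP26A1, the retinoic acid hydroxylase that clears the ligand (ENSG00000095596.11, hg38 chromosome 10, 93073475 to 93077885), had 25 counts in the 3 control libraries together and 31285 in the treated ones. Its TMM-normalized CPM went from 0.319 ± 0.0538 to 279.2 ± 5.69 (SD, n = 3 libraries per group), a log2 fold change of 9.75 (SE 0.26; edgeR quasi-likelihood adjusted p = 3.52e-39) and the smallest adjusted p of all genes tested. Its paralog CYP26B1 (ENSG00000003137.8, chromosome 2, 72129238 to 72147862) rose from 2.86 ± 0.995 to 149.0 ± 4.23 CPM, or 51.8-fold. STRA6, the membrane receptor for retinol bound to its plasma carrier (ENSG00000137868.18, chromosome 15, 74179466 to 74212267), rose from 0.447 ± 0.254 to 123.5 ± 2.66 CPM, and DHRS3, a retinaldehyde reductase (ENSG00000162496.8, chromosome 1, 12567910 to 12618210), from 6.72 ± 1.19 to 218.4 ± 2.79 CPM. Of 20 tested members of the list 14 rose, 4 fell and 2 did not pass, with a median log2 fold change of 1.54 (camera adjusted p = 0.0264; adjusted p = 0.218 with an estimated correlation). The camera call was lost when libraries were scaled by their totals (adjusted p = 0.142), where the median was 1.86. Among members named after their values were seen, HOXA1, a homeobox gene that retinoic acid induces, rose 17.6-fold, and TGM2, a transglutaminase, 7.45-fold. The 4 members that fell were the receptors RARA (fell by 1.28 on the log2 scale) and RARG (fell by 1.15), the carrier protein CRABP2 (fell by 0.81) and the receptor kinase RET (fell by 1.53). RARB, another retinoic acid receptor, had 0 counts in all 6 libraries and was not tested.

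Genes of the vitamin D receptor response mostly rose. CYP24A1, the 24-hydroxylase that degrades active vitamin D (ENSG00000019186.9, chromosome 20, 54153446 to 54173986), went from 7.70 ± 0.392 to 12.5 ± 0.873 CPM, a log2 fold change of 0.70 (SE 0.11; edgeR adjusted p = 4.29e-07). VDR itself stood at 19.6 ± 0.218 and 18.9 ± 1.61 CPM, a log2 fold change of -0.05 (SE 0.08; edgeR adjusted p = 0.535), which became a rise of 0.27 with library totals (adjusted p = 0.00282) and of 0.27 with the GC correction. Of 18 tested members 14 rose, 3 fell and 1 did not pass, with a median log2 fold change of 1.48 (camera adjusted p = 0.0145; adjusted p = 0.352 with an estimated correlation). GADD45A, a growth arrest gene, rose from 7.80 ± 1.95 to 64.7 ± 2.42 CPM and ATP2B1, a plasma membrane calcium pump, from 37.2 ± 0.486 to 114.4 ± 2.77 CPM. Named after their values were seen, TRPV6, an epithelial calcium channel, rose 59.5-fold from 0.103 ± 0.0465 CPM and KLK6, a kallikrein protease, 9.20-fold. CD14, a monocyte co-receptor, had 0 counts in the control group and 92 in the treated group, at least 21.4-fold higher against a floor of 3 counts over the group. FBP1, a gluconeogenic enzyme, fell by 1.62 on the log2 scale, and LRP5, a Wnt co-receptor, fell by 1.02. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, fell by 0.25 (92.2 ± 3.46 to 77.5 ± 2.55 CPM; edgeR adjusted p = 1.78e-06), a direction that flipped to 0.08 with library totals and to 0.25 with the GC correction.

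Receptors and carriers of the 2 vitamins went both ways. Of 7 tested nuclear receptors of retinoids and vitamin D, 5 fell, RORC rose 5.29-fold and VDR did not pass, and the list itself missed the threshold (median -0.74; camera adjusted p = 0.0851). RXRA, the shared partner of RAR and VDR, went from 177.5 ± 7.30 to 65.4 ± 2.25 CPM. Of 13 tested genes of retinoid and vitamin D uptake and metabolism 6 rose, 4 fell and 3 did not pass (median 0.09; camera adjusted p = 0.769). ALDH1A2, a retinaldehyde dehydrogenase that makes retinoic acid and was named after its values were seen, had 0 counts in the control group and 57 in the treated group. DHCR7, which removes the vitamin D precursor by reducing it to cholesterol, fell by 2.15 on the log2 scale.

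Estrogen receptor target and luminal genes were mostly lower in treated cells. GREB1, a cofactor and target of the estrogen receptor, went from 2004 ± 12.8 to 467.7 ± 18.4 CPM, PGR, the progesterone receptor, from 168.2 ± 6.03 to 27.6 ± 1.73 CPM, and TFF1, a secreted trefoil peptide, from 1667 ± 25.7 to 826.8 ± 24.9 CPM. ESR1, the estrogen receptor gene, fell 2.12-fold (245.3 ± 6.42 to 115.5 ± 4.81 CPM; edgeR adjusted p = 4.35e-24). Of 24 estrogen receptor targets 16 fell, 5 rose and 3 did not pass, with a median log2 fold change of -1.14 (camera adjusted p = 0.0105; adjusted p = 0.192 with an estimated correlation). The risers included STC2 (6.06-fold), a stanniocalcin that also stands in the integrated stress response list, and NRIP1, a corepressor that also stands in the retinoic acid list. Among 15 luminal identity genes 11 fell, 3 rose and 1 did not pass (median -0.37; camera adjusted p = 0.0348; adjusted p = 0.254 with an estimated correlation). The camera call of this list was lost with library totals (adjusted p = 0.079). Most of its members were abundant, and abundant genes mostly fell. Protein-coding genes with a mean of 161.2 to 9562 CPM had a median log2 fold change of -0.51. The luminal median may thus reflect expression level, which camera did not take into account. KRT8, KRT18 and KRT19, the keratins of simple epithelia, had log2 fold changes of -1.90, -1.58 and -1.57. KRT8 and KRT18 overlap on opposite strands over 525 bp of exon, and the strand setting of the counting is not stated, so reads in that stretch cannot be assigned. GATA3 fell by 0.59, whereas FOXA1 did not pass (264.9 ± 6.32 and 275.9 ± 3.23 CPM) and EPCAM, an epithelial adhesion molecule, rose 1.71-fold. Of 11 basal and mesenchymal genes 3 rose, 5 fell and 3 did not pass (median -0.14; camera adjusted p = 0.769): FN1, fibronectin, rose 4.51-fold, while SNAI1 fell by 2.14 and KRT17 fell by 3.34.

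Genes of the unfolded protein and integrated stress responses mostly rose. HSPA5, the main chaperone of the endoplasmic reticulum (ENSG00000044574.7, chromosome 9, 125234853 to 125241382), went from 519.6 ± 18.8 to 1978 ± 42.3 CPM, HSP90B1 from 322.2 ± 6.97 to 1047 ± 17.9 CPM and SEL1L, of the degradation machinery of that compartment, from 52.0 ± 0.486 to 194.1 ± 5.57 CPM. All 20 tested genes of the unfolded protein response rose (19 with the GC correction, where 1 fell), with a median log2 fold change of 1.32 (camera adjusted p = 2.86e-07; adjusted p = 0.116 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signaling (ENSG00000168209.4, chromosome 10, 72273919 to 72276036), rose 17.5-fold, from 26.3 ± 2.80 to 460.9 ± 3.10 CPM. VEGFA, an angiogenic factor, rose 4.51-fold and WARS1, the tryptophanyl-tRNA synthetase, 3.60-fold. Of the 26 genes of the integrated stress response, which ATF4 drives, 22 rose and 4 fell (median 1.17; camera adjusted p = 1.3e-05; adjusted p = 0.116 with an estimated correlation). DDIT3 (CHOP) and CHAC1, named after their values were seen, rose 62.7-fold and 36.3-fold, and ATF4 itself 1.73-fold. The members that fell were the transcription factor ATF5 (fell by 1.76), the amino acid transporter SLC7A5 (fell by 0.46, but rose by 0.17 with the GC correction) and the serine pathway enzymes PHGDH (fell by 0.21) and SHMT2 (fell by 0.12).

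Of 24 genes of the NRF2 oxidative stress response 17 rose, 6 fell and 1 did not pass, with a median of 0.68 (camera adjusted p = 0.0348; adjusted p = 0.218 with an estimated correlation). HMOX1, heme oxygenase, rose 12.8-fold, SLC7A11, the cystine transporter, 5.96-fold and ABCC3, an efflux pump, 5.36-fold, whereas G6PD, TKT and TALDO1, enzymes of the pentose phosphate pathway, fell. The camera call of the list was lost under a filter of 1 CPM in 3 libraries (median 0.55, adjusted p = 0.0519). It was also lost with library totals (median 1.01, adjusted p = 0.13). Of 14 heat shock genes 8 fell, 5 rose and 1 did not pass (median -0.45, camera adjusted p = 0.2). With the GC correction 11 fell and 1 rose (camera adjusted p = 0.000621). HSPB1 went from 6972 ± 104 to 2124 ± 51.7 CPM and BAG3 from 272.0 ± 6.13 to 61.8 ± 0.788 CPM. HSPA1A also fell, although its near-identical copy HSPA1B makes its own count uncertain. Among 4 tested metallothionein-list genes, too few for the set test, MT1F and the zinc exporter SLC30A1 rose 1.89-fold and 1.46-fold, and MT2A did not pass (217.3 ± 2.47 and 208.9 ± 8.58 CPM). The SLC30A1 call was lost with the GC correction. MT1X fell by 0.30 on the log2 scale, a direction that flipped to 0.03 with library totals, and its call was lost with the GC correction.

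Sterol and fatty acid synthesis genes mostly fell. LDLR, the low-density lipoprotein receptor (ENSG00000130164.13, chromosome 19, 11089418 to 11133820), went from 438.2 ± 4.30 to 32.8 ± 0.839 CPM, a log2 fold change of -3.74 (SE 0.03; edgeR adjusted p = 4.18e-38). PCSK9, the secreted protein that sends that receptor to degradation, fell by 4.75, and FDFT1, squalene synthase, fell by 2.69 (853.5 ± 4.86 to 132.6 ± 0.868 CPM). MVD, of the mevalonate pathway, fell by 2.81. Of 24 genes in the cholesterol synthesis list 21 fell, 2 rose and 1 did not pass, with a median of -1.57 (camera adjusted p = 2.62e-06; adjusted p = 0.116 with an estimated correlation). The 2 risers were the sterol enzymes SC5D (2.28-fold) and HSD17B7 (2.08-fold). FASN, fatty acid synthase, went from 4060 ± 33.9 to 1128 ± 53.3 CPM, and SCD, stearoyl-CoA desaturase, from 1387 ± 21.8 to 480.1 ± 2.70 CPM. Of 16 fatty acid synthesis and LXR target genes 12 fell, 2 rose and 2 did not pass (median -0.94; camera adjusted p = 0.00338; adjusted p = 0.303 with an estimated correlation). The LXR target ABCG1, a sterol exporter, rose 2.84-fold, whereas SREBF1 of the same list fell by 0.92. ABCA1, also in that list and named after its values were seen, did not pass (26 counts in the control group and 29 in the treated group). Fatty acid oxidation genes showed no group call: 7 of 12 rose, 3 fell and 2 did not pass (median 0.38; camera adjusted p = 0.333), with ANGPTL4 up 5.46-fold. Hypoxia and glycolysis genes divided, with 12 of 25 higher, 8 lower and 5 not passing (median 0.15; camera adjusted p = 0.493): NDRG1, a hypoxia-inducible gene, rose 12.4-fold, while the glycolytic enzymes TPI1 and GAPDH had log2 fold changes of -1.58 and -1.02.

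**Figure D3:**
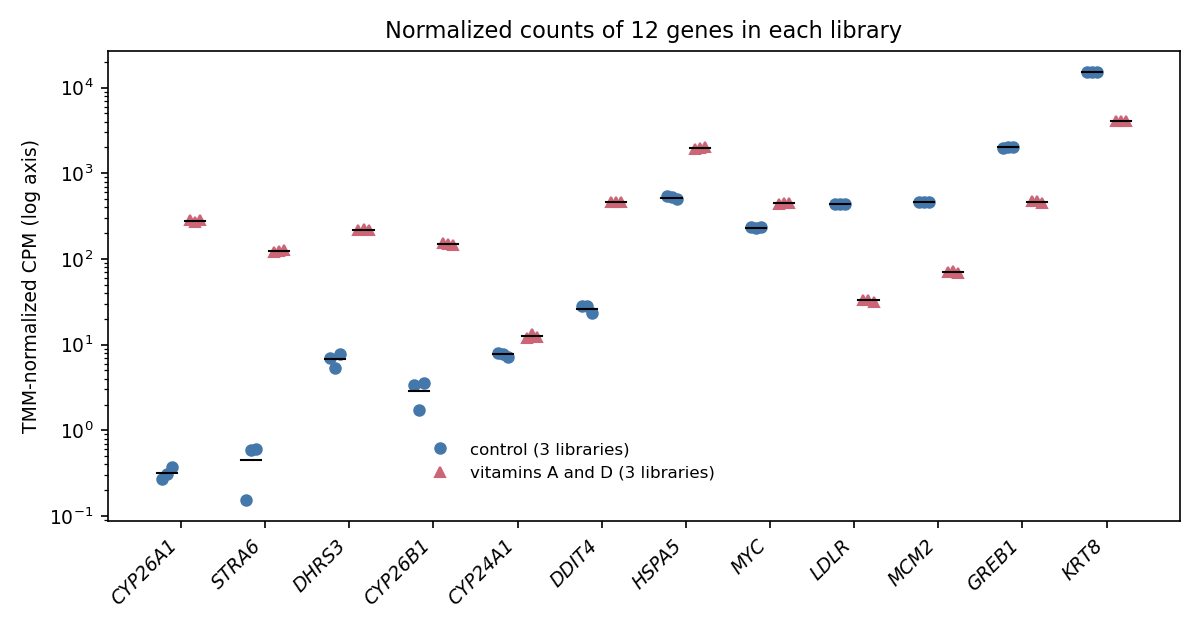
TMM-normalized CPM (log axis) of 12 genes in each of the 6 libraries; blue circles are control libraries, red triangles are treated libraries, and black bars are group means. In each of the 12 genes the 3 treated libraries lay on one side of the 3 control libraries, from CYP26A1 (0.319 to 279.2 CPM) down to KRT8 (15072 to 4052 CPM).

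DNA replication and histone genes mostly fell. MCM2, a subunit of the replicative helicase (ENSG00000073111.13, chromosome 3, 127598410 to 127622436), went from 461.4 ± 6.11 to 70.8 ± 2.17 CPM, MCM7 from 1131 ± 23.1 to 276.8 ± 4.11 CPM and MCM5 from 293.2 ± 9.02 to 58.1 ± 1.94 CPM. Of 26 genes of G1/S and DNA replication 24 fell and 2 rose, with a median of -1.60 (camera adjusted p = 1.62e-07; adjusted p = 0.128 with an estimated correlation). CCND1, cyclin D1, fell 1.86-fold, and the 2 risers were CDK6 (2.38-fold) and CDC6 (1.14-fold). Of 25 genes of G2/M and mitosis 15 fell, 6 rose and 4 did not pass, and the list missed the threshold (median -0.17; camera adjusted p = 0.0851). It passed with no low-count filter (adjusted p = 0.0377) and with the GC correction (adjusted p = 0.00028), where 19 fell and 1 rose. FOXM1, a mitotic transcription factor, fell by 1.38, PLK1 fell by 1.14 and MKI67, the Ki-67 proliferation antigen, fell by 0.78, while TOP2A stood at 174.7 ± 10.8 and 174.2 ± 4.62 CPM and did not pass. Of 21 replication-dependent histone genes 20 fell and 1 did not pass (median -1.82; camera adjusted p = 0.000629; adjusted p = 0.254 with an estimated correlation). Most transcripts of this class lack a poly(A) tail and many are near-identical, so single histone genes are uncertain in a poly(A)-based count. MYC rose 1.92-fold (232.5 ± 1.53 to 445.3 ± 4.16 CPM; edgeR adjusted p = 4.2e-25). MYC targets and ribosome biogenesis genes went both ways, 11 of 23 higher, 10 lower and 2 not passing. Their median and mean were both 0.02 while the camera direction was down (adjusted p = 0.984).

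Apoptosis genes went both ways. BAX, a pro-apoptotic effector, went from 82.2 ± 2.23 to 51.5 ± 2.47 CPM (fell by 0.68; edgeR adjusted p = 4.97e-15), and BCL2, its anti-apoptotic counterpart, from 60.6 ± 0.618 to 21.2 ± 0.184 CPM (fell by 1.52; edgeR adjusted p = 1.75e-22). Of 24 pro-apoptotic genes 12 rose, 10 fell and 2 did not pass (median 0.20; camera adjusted p = 0.927): CYCS, cytochrome c, rose 2.07-fold and TNFRSF10B, a death receptor, 1.86-fold, while BOK fell by 1.65 and BAD fell by 0.97. BAD shares 404 bp of exon with GPR137 on the other strand, so its count is uncertain. Of 11 anti-apoptotic genes 6 rose and 5 fell (median 0.34; camera adjusted p = 0.965), BIRC2 rising 3.37-fold and BIRC5, survivin, falling 2.09-fold. Their mean was 0.29 and limma's fry test, which asks whether members move on balance one way, gave the direction down against up in camera (fry adjusted p = 2.49e-05). Of 24 p53 targets 16 rose, 6 fell and 2 did not pass (median 0.39; camera adjusted p = 0.105), with GDF15, a stress cytokine, up 8.85-fold and SESN2 7.97-fold. SESN2 also stands in the integrated stress response list. BAX and CDKN1A, also in the p53 list, fell by 0.68 and 0.25, the latter a direction that flipped with library totals and with the GC correction.

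Most tested inflammatory genes rose. LCN2, lipocalin 2 (ENSG00000148346.11, chromosome 9, 128149071 to 128153453), had 3 counts in the control group and 2580 in the treated group, a ratio of 600.4 with a 95% counting interval of 205.2 to 2913. TNFAIP3, a feedback inhibitor of NF-kB, rose 11.1-fold from 0.512 ± 0.125 CPM, and ICAM1, an adhesion molecule, 2.98-fold. Of 12 tested NF-kB and inflammatory genes, from 23 listed, 9 rose, 1 fell and 2 did not pass (median 2.51; camera adjusted p = 0.0145; adjusted p = 0.218 with an estimated correlation). Interferon response genes went both ways, with 7 of 21 higher, 8 lower and 6 not passing. Their median was 0.33 and mean 0.10, while the camera direction was down (adjusted p = 0.769); IFIH1, a sensor of double-stranded RNA, fell by 1.34 and STAT1 rose 1.45-fold. Of 17 TGF-beta and SMAD targets 10 rose, 6 fell and 1 did not pass (median 0.52; camera adjusted p = 0.382), led by the matrix protein TGFBI (17.4-fold) and ID1 (4.28-fold). Of 13 Wnt targets 2 rose, 8 fell and 3 did not pass (median -0.30; camera adjusted p = 0.317); the risers were BAMBI (3.60-fold) and MYC. Among 27 immediate early genes 11 rose, 12 fell and 4 did not pass (median 0.06; camera adjusted p = 0.984): ATF3 rose 5.92-fold and DUSP4 2.10-fold, while JUNB fell by 1.15 and JUND fell by 1.01, the latter a call lost with the GC correction. Of 9 aryl hydrocarbon receptor targets 6 rose, 2 fell and 1 did not pass (median 0.68; camera adjusted p = 0.235), with AHRR up 3.31-fold and CYP1B1 2.15-fold.

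Most ribosomal protein and mitochondrial transcripts took a smaller share in treated cells. RPS2 went from 8421 ± 98.8 to 3568 ± 92.0 CPM and RPL8 from 3347 ± 40.5 to 1696 ± 30.1 CPM. Of 30 cytosolic ribosomal protein genes 24 fell, 4 rose and 2 did not pass (median -0.47; camera adjusted p = 0.000159; adjusted p = 0.505 with an estimated correlation). Their many processed pseudogenes can take or lend reads. RPS2 and RPL8 were abundant, and protein-coding genes with a mean of 161.2 to 9562 CPM had a median log2 fold change of -0.51. The median of the ribosomal list may thus reflect expression level, which camera did not take into account. MT-CO3, a cytochrome oxidase subunit, went from 9677 ± 241 to 4150 ± 235 CPM and MT-CYB, cytochrome b, from 9790 ± 247 to 5312 ± 366 CPM. Of the 13 protein-coding genes of mitochondrial DNA 12 fell and MT-ND5 rose 1.12-fold (median -0.87; camera adjusted p = 0.00212; adjusted p = 0.505 with an estimated correlation), while all 13 fell with the GC correction. Mitochondrial transcripts held 7.56% to 7.77% of counts in control and 5.93% to 6.57% in treated libraries. Nuclear-encoded oxidative phosphorylation genes missed the threshold, with 12 of 22 lower, 4 higher and 6 not passing (median -0.24, camera adjusted p = 0.108). With the GC correction 17 fell and 1 rose (camera adjusted p = 0.000302). UQCRC1 fell by 1.23 and SDHA fell by 1.09. Of 23 autophagy and lysosome genes 12 rose, 9 fell and 2 did not pass (median 0.17; camera adjusted p = 0.794): MAP1LC3B, the LC3 protein of autophagosomes, rose 3.30-fold and CTSD, a lysosomal protease and estrogen target, fell by 1.41.

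Several of the largest changes were in genes near silence in control cells. CDH5, the cadherin of endothelial junctions (ENSG00000179776.17, chromosome 16, 66366690 to 66404784), had 5 counts in the control group, 4 of them in a single library, and 15793 in the treated group, or 140.8 ± 5.43 CPM, a log2 fold change of 11.02 (SE 0.67; edgeR adjusted p = 4.32e-35). Against a floor of 3 counts over the group, KLHDC7B (0 and 433 counts) was at least 100.8-fold higher, CEACAM1, an adhesion molecule (0 and 256 counts), at least 59.6-fold, KCNE4, a potassium channel subunit (0 and 255 counts), at least 59.3-fold and BEX5 (0 and 227 counts) at least 52.8-fold. INHBE, an inhibin subunit, had 1 and 812 counts, a ratio of 566.8 with a 95% counting interval of 101.5 to 22417. CCDC33 had 3 and 2950 counts (ratio 686.5, interval 234.7 to 3331) and CP, ceruloplasmin, 2 and 293 counts (ratio 102.3, interval 28.1 to 848.4). CCDC33 shares 519 bp of exon with STRA6 on the other strand, and CP 1420 bp with HPS3, so both counts are uncertain. HPS3 had 5032 counts over the 6 libraries while CP had 2 in the control group. HPS3 reads are thus an unlikely source of the CP rise unless HPS3 rose as steeply. LIMCH1, an actomyosin regulator, rose 107.9-fold from 8 counts in the control group, 7 of them in a single library. Among the falls MGAT3, a glycosyltransferase that adds bisecting N-acetylglucosamine (ENSG00000128268.11, chromosome 22, 39457012 to 39492194), went from 884 counts in the control group to 12, or 11.3 ± 0.670 to 0.108 ± 0.0512 CPM, a log2 fold change of -6.67 (SE 0.43; edgeR adjusted p = 2.61e-22). Log2 fold changes were -5.81 for FOXI1, -5.28 for LINC02747, -5.19 for B3GNT6 (9 counts in the treated group, 6 of them in a single library), -4.87 for PLXNA4, -4.54 for CDH18, -4.38 for COL9A2 and -4.32 for NYNRIN. More abundant genes in this group were CLIC3, an intracellular channel protein (144.8 ± 4.24 to 5.60 ± 0.210 CPM), PCDH19, a protocadherin (94.97 ± 3.81 to 4.95 ± 0.785 CPM), and GSG1L, an AMPA receptor auxiliary protein (64.0 ± 0.730 to 2.84 ± 0.390 CPM). Among the 6 smallest adjusted p-values, TUBB4B, a beta-tubulin, fell by 2.88 (1570 ± 10.5 to 213.3 ± 4.66 CPM).

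Most markers of other cell types had too few counts to test. Of 12 fibroblast and stromal genes only 2 had enough counts to test: COL1A1 fell by 1.12 on the log2 scale, and COL3A1 did not pass (log2 fold change 0.86). Of 13 immune and blood cell genes 2 were tested, CD14, given with the vitamin D list, and HBA1. HBA1 fell by 1.31, a call lost with the GC correction, and has the near-identical copy HBA2. Of 8 endothelial genes 4 were tested, and while CDH5 rose, ERG, VWF and ENG fell, with log2 fold changes of -1.18, -1.67 and -0.42. The value of ENG turned to 0.29 with the GC correction, and its call was lost with library totals (-0.10, edgeR adjusted p = 0.475).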

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

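The GC correction and the scaling by library totals were chosen after seeing the data. Over the other counting settings 11554 changed genes became 10530 to 11902, except that a test against a log2 fold change of 0.5 left 6862 (3574 higher, 3288 lower), a smaller number because it asks for larger changes. Leaving out each library in turn gave 11145 to 11479 genes and 14 lists each time. Of 2000 comparisons of a named gene with its value under another setting, 1987 kept direction and side of the threshold, and of 416 for lists 368 did. The 14 called lists became 0 (0 higher, 0 lower) with estimated correlations and 26 (11 higher, 15 lower) with fry, which sets a list against no other genes. All 14 kept their call and direction with the GC correction, whereas with library totals the retinoic acid, luminal and NRF2 lists lost it.

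Of all genes called in both fits, 8140 of 9306 kept their direction with the GC correction and 9758 of 10191 with library totals. Among the named genes and lists, direction turned for uncalled results near 0 and a few called genes. Fry gave the opposite direction to camera for retinoid and vitamin D uptake and metabolism (median 0.0875), basal and mesenchymal genes (median -0.14), anti-apoptotic genes (median 0.34) and autophagy and lysosome genes (median 0.17). With library totals camera's direction turned from up to down for pro-apoptotic genes (median 0.53), anti-apoptotic genes (0.67) and immediate early genes (0.38). It turned from down to up for MYC targets (0.34). With the GC correction it turned down for anti-apoptotic genes (0.0373) and up for MYC targets (0.0111). For immediate early genes it turned down with no low-count filter (0.0419) or a filter of 1 CPM in 3 libraries (0.0172). Camera compares per-gene test statistics of a list, not its median, with those of all other genes, so the 2 can differ in direction. With library totals the median of all tested genes was 0.36. That lay below the medians of the lists that turned down and above that of MYC targets, so a shifted center does not explain these turns. Leaving out each library, the median of the list immediate early genes ran from -0.0140 to 0.0721, that of the list MYC targets and ribosome biogenesis from -0.0293 to 0.0431, and the log2 fold change of VDR from -0.12 to 0.0120, the last without treated replicate 3. Log2 fold changes turned with the GC correction for VDR (0.27), CDKN1A (0.25), SLC7A5 (0.17) and ENG (0.29), and with library totals for VDR (0.27), CDKN1A (0.0755) and MT1X (0.0263). Library totals raise all log2 fold changes together, and beyond that the cause was not tested. Depth limits genes with few control counts, such as CDH5 and INHBE, whose rise is loose in size.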

Other observations

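All tests in this part were chosen after the data were seen, except the intron GC test, which was written down before its result. Of 15 gene families looked at, some are given below, picked for their values; no test was made, and 78.6% of all tested genes changed. Several others were closer to balance: of 36 proteasome genes 16 rose and 16 fell, of 14 keratins 8 and 6, of 19 DUSP phosphatases 9 and 6, and of 9 claudins 3 and 4. With the GC correction these numbers were 9 and 21, 8 and 6, 11 and 5, and 6 and 2, so the balance depended on it. Of 17 tubulin genes 11 fell and 1 rose (median log2 fold change -1.19), among them TUBB (3741 ± 38.4 to 918.6 ± 7.51 CPM; SD, 3 libraries per group) and TUBA1B (2059 ± 24.8 to 666.2 ± 11.4 CPM). Of 18 cytosolic aminoacyl-tRNA synthetase genes 16 rose and 2 fell (median 0.80), with SARS1 up 2.98-fold and GARS1 2.53-fold. WARS1 and CARS1 of that family also stand in the integrated stress response list. Homeobox genes of the HOXB cluster rose in 4 of 5 tested (median 4.68), among them HOXB2, which rose 25.7-fold from 23 counts in the control group, and those of the HOXA cluster in 5 of 9 with 0 lower (median 0.62; HOXA1, HOXA4 and HOXA5 also stand in the retinoic acid list), whereas of 8 HOXC genes 2 rose and 4 fell. Zinc finger genes with ZNF symbols were higher in 279 and lower in 82 of 435 tested (median 0.49). Their median GC content was 42.9%, and with the GC correction the numbers were 214 and 89 (median 0.22). The 3 tested AKR1C genes, aldo-keto reductases that metabolize steroids and retinaldehyde, all rose (median 4.73) and also stand in the NRF2 list, although their sequences are close enough to share reads.

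Of the 107 genes that rose at least 16-fold, 6 adjacent pairs of tested genes both did so, against a mean of 0.749 pairs and a highest of 5 when gene order was permuted 1000 times. The pairs were AKR1C1 with AKR1C2, AKR1C2 with AKR1C3, ISLR2 with STRA6, STRA6 with CCDC33, HOXB2 with HOXB3, and KCNE4 with SCG2. The permutations treat genes as independent, and no test was made of read sharing among the AKR1C genes, which are close in sequence. Without the AKR1C pairs and the overlapping pair of STRA6 and CCDC33, 3 pairs remain, for which no permutation was run.

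The labelled grouping gave 11554 changed genes, and the highest of the other 9 ways to split the 6 libraries 3 against 3 gave 0 by edgeR. Each of those 9 splits mixed control and treated libraries on both sides, so the group difference entered the spread and left little room for calls. The 0 is thus no null against which to set the 11554. With 10 splits, 1 of which gave as many as the real one, a share under 0.05 cannot be reached.

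The fold changes fell with transcript GC content across 12612 protein-coding genes, which are not independent replicates (Spearman's rho -0.56, 95% bootstrap interval -0.573 to -0.545). Taken against the mean of all 6 libraries, the slope of log2 CPM on GC was 0.26 to 0.267 per 10 points of GC in the 3 control libraries and between -0.275 and -0.252 in the 3 treated ones; the opposite signs follow from the centering, and only the difference between groups, larger than the spread within them, is informative. Transcript length and expression level are argued against as the cause, since rho was -0.5415 at fixed length and -0.5589 at fixed mean CPM. A GC bias of the sequenced fragments as the only cause would leave the GC of introns, which are not in mature mRNA, unrelated to the fold change at fixed transcript GC; that partial rho was -0.1233 (interval -0.143 to -0.108, 11434 genes), away from 0 yet smaller in size than the -0.241 for transcript GC at fixed intron GC. A library effect and a response of the cells that favors genes in AT-rich regions cannot be told apart, because the slope differed between the groups far more than within them and an imperfect measure of transcript GC could leave part of its effect with introns.

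The called gene lists may have owed their direction to that trend. With the GC trend of each library removed, 14 of the 14 lists stayed past the threshold in the same direction, with medians from -1.58 for G1/S and DNA replication to 2.70 for NF-kB and inflammatory genes, which argues against the trend as their whole cause. The correction left medians of 1.77 for the retinoic acid response, 1.21 for the unfolded protein response and -1.34 for cholesterol synthesis. Fold changes also ran with expression level. The median log2 fold change was 0.23 for protein-coding genes with a mean of 0.17 to 1.48 CPM and -0.51 at 161.2 to 9562 CPM. The trend of fold changes with expression level was not removed in any test of the lists. It stays open as a cause of calls for lists of abundant genes with modest falls, such as luminal identity (median -0.37) and cytosolic ribosomal proteins (median -0.47). An effect of the treatment on these groups stays open as a hypothesis. None of the 14 passed with estimated correlations, though for 5 of them, such as the retinoic acid response (-0.011), the estimate was below the preset 0.01, so correlation between members does not account for those losses.

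CCDC33 rose from 3 to 2950 counts beside STRA6, which it overlaps on the opposite strand over 519 bp. In the treated libraries its counts were 22.4%, 19.9% and 21.6% of those of STRA6. The lowest 95% exact bound of that ratio, 18.55%, lies above the 6.77% of STRA6 exon sequence that overlaps CCDC33. It lies below the 24.1% of the STRA6 transcript with the largest overlap, and only 10 of 22 STRA6 transcripts overlap CCDC33. STRA6 reads could reach the ratio if that transcript were the main one and shared reads were counted for CCDC33. Other overlapping genes argue against such counting in their own pairs. Over the 6 libraries SLC7A11-AS1 had 6 counts beside 23280 of SLC7A11 (865 bp shared), and FAM166A had 124 beside 146724 of TUBB4B (124 bp shared). No value here shows which STRA6 transcript was expressed, and a rise of CCDC33 itself stays open as well.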
